A study of Drosophila melanogaster with 2 samples.

How the data were processed

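Binding of the Drosophila melanogaster protein CG10348, encoded by a predicted C2H2 zinc-finger gene, was measured by ChIP-seq in whole pupae aged 2 days. Per the labels, the flies were transgenic and carried CG10348 fused to enhanced GFP, and chromatin was sheared by sonication and precipitated with an antibody against GFP. The 2 biological replicates formed 1 group, and the labels gave their replicate numbers. No second condition was present, so the comparisons were between the replicates, between peaks and other regions of the same assay, and between groups of genes.

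The authors deposited lists of regions ranked by the irreproducible discovery rate (IDR), which scores how alike a region ranks in a pair of peak lists, and lists thresholded on that rate. Per the deposited text that accompanied each sample, every list was derived from the replicates' alignments and the same control, and the thresholded lists from a further file whose role was not stated. The peak caller and aligner were not given in the sources used here. Per the labels, coordinates were on the dm6 assembly. One ranked list of the pooled samples carried a signal for each member of a replicate pair and held all 1814 peaks of the conservative thresholded list. The second ranked list of the pooled samples held all 1934 peaks of the other thresholded list, called the optimal set here. Each replicate had its own ranked and thresholded lists. The control was not analysed here.

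The deposited signal value of a region was the authors' peak strength, with a scaling that was not stated, and it was used only to describe and rank regions within a list. The deposited score was the authors' scaled IDR, capped by the file format, and the thresholded lists began at a score of 830, which corresponds to an IDR of 0.01. The deposited −log10 values gave the IDR itself in the ranked lists. The summit was taken from the offset that the authors deposited for each peak. No read counts were in the deposited lists, so depth was unknown, and the binomial intervals given here (Wilson, 95%) covered counting error of peaks and genes only, as did the upper limit for a chromosome without a summit, set at 3 counts of the total. Both replicates were set against the same control, so their agreement may come in part from it. The p-values measured departures from a background within these 2 samples, and regions are not independent replicates.

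Genes, transcripts and TSSs of 13945 protein-coding genes on 2L, 2R, 3L, 3R, 4 and X came from Ensembl annotation of the same assembly, and sequence from the RefSeq genome of that assembly. All deposited coordinates on these arms lay within the lengths of the reference chromosomes. Tests used the 1799 conservative peaks on these arms, and the remaining 15 conservative peaks entered peak numbers alone. A promoter summit lay within 1 kb of a TSS. The background was 133555 ranked regions that scored under 830 and touched no conservative peak.

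Replicate peaks were compared by an overlap of at least 1 bp against 1000 shufflings of positions within chromosomes (one-sided permutation test). Location and chromosome arms were tested by two-sided Fisher's exact tests. The 36 gene lists were tested by two-sided Fisher's exact tests on genes with a promoter summit, and by two-sided exact binomial tests on the 1609 summits whose nearest TSS lay within 10 kb, with the expectation set by each list's share of bases. Of 1486 list entries, 24 names had no match in the annotation and were left out. The 29 consensus sequences were sought on both strands in the 100 bp centred on each summit and in windows centred 300 bp to each side, with an exact sign test against 1 of both flanks, chosen pseudo-randomly from the position. Sequences of 6 and 8 bases were ranked on 2L, 2R and 4, and the top 10 of each length were tested on 3L, 3R and X. Adjusted p-values are Benjamini-Hochberg values within each family, and 0.05 was the threshold. Coordinates are given from 1.

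The lists, consensus sequences, tests and most alternatives were fixed before the data were examined. Named genes were CG10348, the gene with the nearest TSS for each of the 25 conservative peaks of highest signal, and, for each list past the threshold, up to 4 members with the strongest peaks; any other name was chosen after its values were seen. Alternatives covered the optimal set, each replicate's peaks alone, the stronger peaks, other distances, windows and backgrounds, and stricter overlaps. Alternatives added after seeing the data left out 77 conservative peaks that rested on the same pair of replicate peaks as a stronger peak, counted each gene once, compared the lists with the strongest regions that did not pass IDR by Fisher's exact test, applied an IDR of 0.001, and replaced flanks by copies of the summit windows shuffled with their dinucleotide counts kept.

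The statistics were tested on simulated data of 1799 shuffled peaks. A planted list was found in 20 of 20 simulations by the promoter test, the nearest TSS test and the test with each gene counted once, while 2, 1 and 0 of 720 unplanted lists were called. A planted consensus was found in 20 of 20 simulations, with 2 of 560 other consensus tests called. Planting used a single strength, with summits placed exactly at TSSs of list genes or on the consensus. The other simulated peaks lacked the promoter concentration, clustering and AT-rich centres of the real peaks. These rates therefore do not carry over to weaker effects or to the real distribution of peaks. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.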

Results

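ChIP-seq against GFP was performed on whole pupae aged 2 days that expressed a CG10348-eGFP fusion, with 2 biological replicates in 1 group. The authors called 1284 reproducible peaks in replicate 1 and 1027 in replicate 2, and 1814 in the conservative pooled set, which covered 567 kb. The optimal set held 1934 peaks, 1.07 times the conservative number, and replicate 1 had 1.25 times as many peaks as replicate 2. The optimal set did not contain the whole conservative set: it overlapped 1593 of the 1799 conservative peaks on the main arms (88.5%) and missed 206. Depth was unknown because the lists gave no read counts. Positions are on dm6, and signal is the authors' value, given as pooled signal and then for each replicate's own list.

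The strongest peak lay at the promoter of CG14100 (FBgn0036889). Its pooled signal, 1064, was at 3L 19590475 to 19590757, 96 bp upstream of the TSS, with 538 in replicate 1 and 526 in replicate 2. The next was 932 at X 2703744 to 2704019, 39 bp upstream of Ugalt (FBgn0024994), which encodes a UDP-galactose transporter, with 523 and 414. CG7601 (FBgn0027583) followed with 772 at 3R 29736714 to 29736988, 104 bp upstream of its TSS, with 389 and 381. These 3 summits were intergenic.

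The 25 strongest also included peaks at transcription and chromatin regulators, without a test of their share. Adf1 (FBgn0284249), a Myb-related transcription factor, had a pooled signal of 642 in an intron at 2R 6662937 to 6663195, 796 bp into the gene. Trl (FBgn0013263), which encodes GAGA factor, had 541 in an intron at 3L 14759353 to 14759661. The Polycomb-group gene ph-p (FBgn0004861) had 519.6 at X 2137222 to 2137495, 500 bp upstream of a TSS within an annotated intron. Chro (FBgn0044324), encoding the chromatin protein Chromator, had 488 at 3L 22878778 to 22879005 in an annotated 5' UTR. Among genes of translation, the pooled signal was 595 at mRpL41 and 487 at mRpL23 (mitochondrial ribosomal proteins) and 557 at eIF6, a ribosome biogenesis and initiation factor. CG16753 (662), CG11050 (651), Tcs5 (631), CG4004 (622), CG8320 (606), CG4496 (589) and CG13323 (549.7) completed the upper part of the list by pooled signal. Among them the summits named for CG13323, CG16753, CG4004 and CG11050 lay 11921, 5716, 5089 and 1025 bp from the TSS. The first of these is beyond the limit of 10 kb used for the gene lists. The rest were Shc, CenG1A, HmgZ, PNPase, CG31145, Wdr24, Jwa and Hsp27, the last with 460.3. Of these 25 summits 16 lay within 200 bp of a TSS and 20 within 1 kb, while 13 were intergenic, 10 intronic and 2 in a 5' UTR. The Jwa peak lies in a stretch around the tagged gene where regions that did not pass IDR also had raised signal.

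The replicates called largely the same regions. Of 1268 replicate 1 peaks on the main arms, 776 (61.2%, 95% interval 58.5 to 63.8) were overlapped by a replicate 2 peak, against 0.441% on average after shuffling. Of 1016 replicate 2 peaks, 771 (75.9%, 73.2 to 78.4) were overlapped by a replicate 1 peak, against 0.53%; both permutation p-values were 0.001, the smallest that 1000 shufflings can give. Of the 492 replicate 1 peaks without a partner, 455 (92.5%) overlapped a lower-ranked region of replicate 2, where shuffled positions did so in 33.9% on average, and of the 245 replicate 2 peaks without a partner, 232 (94.7%) overlapped a lower-ranked region of replicate 1, against 29%. Across 1779 conservative peaks with a region in both replicates' own lists, which are regions and not independent replicates, Spearman's rho of signal was 0.706 and Pearson's r of log2 signal 0.82. The log2 ratio of replicate 1 to replicate 2 had a median of 0.28 and an SD of 0.47, so that 1 SD corresponded to 1.38-fold. Over all 138658 ranked regions rho was 0.222, and over the 1910 that passed IDR 0.674. IDR selects regions that rank alike, and both replicates were set against the same control, whose share in this agreement was not split here.

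**Figure D1:**
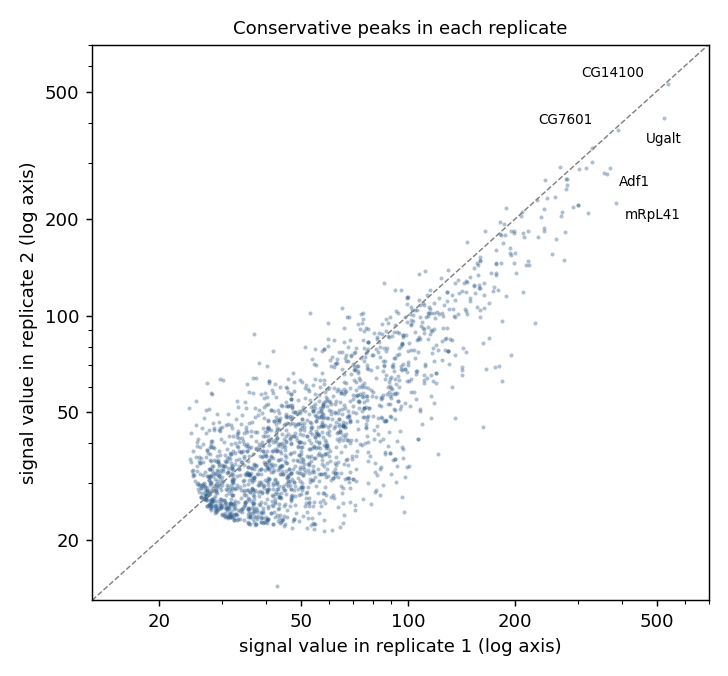
Signal value of each conservative peak in the ranked list of replicate 1 (horizontal, log axis) and of replicate 2 (vertical, log axis), 1 point per peak for 1779 peaks, with the line of equal signal dashed. CG14100, Ugalt and CG7601 lie at the top in both replicates, and replicate 1 values are higher by a median of 1.22-fold.

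Binding was concentrated at promoters. Of 1799 summits, 860 (47.8%, 95% interval 45.5 to 50.1) lay within 1 kb of a TSS, against 21.4% of ranked regions that did not pass IDR (odds ratio 3.36, Fisher's exact test, adjusted p = 2.33e-132) and 20.2% after shuffling. Introns outside promoters held 36% of summits, close to the 34.7% of the background (exact adjusted p = 0.241). Exons outside promoters held 2.5% against 18.2% (exact adjusted p = 1.52e-95), and intergenic sequence 13.7% against 25.7% (adjusted p = 8.4e-35). Within promoters, 662 of 860 summits (77%) lay upstream of the nearest TSS, and the median distance of all 860 from it, in either direction, was 209 bp. Against the strongest regions that did not pass, which were at promoters in 30.4%, the odds ratio fell to 2.1.

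Chromosome X carried more summits and 2R fewer than the background. X held 362 summits (20.1%, 18.3 to 22.0) against 16.8% of regions that did not pass (odds ratio 1.25, Fisher's exact test, adjusted p = 0.000793), and 2R held 280 (15.6%, 14 to 17.3) against 19% (odds ratio 0.787, adjusted p = 0.000793). 3L (22.4%), 3R (23.5%) and 2L (18.5%) did not pass the threshold. Chromosome 4 had 0 of 1799 summits, which allows a share of up to 0.167% (3 counts of the total), against 0.121% of the background. The difference on 2R was not called with replicate 2 alone (exact adjusted p = 0.557), replicate 1 alone (0.226) or the stronger peaks (0.271).

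EGFR and Hippo pathway genes had promoter summits more often, and chemosensory receptor and cuticle genes less often, than other genes. At promoters, 1074 of 13945 protein-coding genes (7.7%) had a summit. Of 23 genes of the EGFR pathway, which signals through Ras and MAP kinase, 8 had a promoter summit (34.8%, 18.8 to 55.1; odds ratio 6.43, Fisher's exact test, adjusted p = 0.00373): Krn, Raf, aop, aos, cic, csw, rho and spi. Of 22 genes of the Hippo growth-control pathway, 6 did (27.3%, 13.2 to 48.2; odds ratio 4.51, exact adjusted p = 0.0473): Diap1, app, dlg1, ds, mats and yki. A promoter summit counted for every gene with a TSS within 1 kb, and the summit at yki was assigned to another gene by nearest TSS. None of 180 odorant, gustatory and ionotropic receptor genes had one (0%, up to 2.09%; exact adjusted p = 2.77e-05), and of 119 cuticle protein genes only Cpr62Ba did (0.84%, 0.148 to 4.61; odds ratio 0.101, adjusted p = 0.0178).

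The other 32 lists did not pass at promoters. They include chromatin and insulator genes (7 of 34, exact adjusted p = 0.0969), sensory organ fate genes (6 of 36, 0.2196), mitochondrial ribosomal proteins (8 of 73, 0.573) and cytosolic ribosomal proteins (6 of 93, 0.981). The EGFR call was lost with replicate 1 alone (exact adjusted p = 0.106) and within 500 bp of a TSS (0.133). The Hippo call was lost with the optimal set (0.151), replicate 1 alone (0.26), the stronger peaks (0.149), the 500 bp limit (0.249) and a background of genes with any ranked region (0.0668).

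Counting every summit by its nearest TSS, 6 lists held more summits than their bases predicted. The EGFR pathway had 30 summits against 6.04 expected (4.97-fold, exact binomial test, adjusted p = 9.1e-11) at 13 of its 23 genes. Its strongest peaks were at Raf, the MAP kinase kinase kinase of the pathway, with a pooled signal of 411 in an intron at X 2300594 to 2300804, and at edl (230.3), sty (186) and spi (165), the last encoding an EGFR ligand. The BMP pathway list had 26 against 7.17 (3.63-fold, exact adjusted p = 7.27e-07) at 11 of 27 genes, led by the receptor gene wit (259), the ligand gene dpp (220.1, in an intron at 2L 2433558 to 2433711), shn (191, with 9 peaks) and cv-c (175). Its members were fixed by hand, and cv-c was also a member of the lists of tracheal and of glial genes. The Hippo pathway had 18 against 5.1 (3.53-fold, exact adjusted p = 8.12e-05) at 11 of 22 genes, led by ds (179), kibra (152), dlg1 (121) and ex (109).

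Chromatin and insulator genes had 11 summits against 3.53 (3.12-fold, exact binomial test, adjusted p = 0.00552) at 7 of 34 genes, led by Trl, ph-p, Chro and Psc (256). The Notch pathway had 11 against 4.38 (2.51-fold, exact adjusted p = 0.0179) at 7 of 30 genes, led by neur (268), numb (179), E(spl)m3-HLH (106) and E(spl)m2-BFM (89.2). Genes of the response to ecdysone, the steroid that drives metamorphosis, had 21 against 10.7 (1.97-fold, exact adjusted p = 0.0172) at 9 of 36 genes, led by E23 (209), Hr4 (189), Eip63E (179.7) and Eip75B (176). The Wnt list (10 against 6.98, exact adjusted p = 0.431) and the hedgehog list (6 against 2.68, exact adjusted p = 0.124) did not pass.

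Another 6 lists held fewer summits than their bases predicted. That expectation spread summits evenly over bases, although summits concentrated near TSSs, so it can be too high for genes with large domains. At promoters only the chemosensory receptors among these lists passed the threshold as lower. With genes matched on domain size and counted once, only the chemosensory list and the dpr, DIP, side and beat list stayed lower. Both had an adjusted p of 0.013 (permutation test). The dpr, DIP, side and beat family of neuronal surface proteins had 1 summit, at dpr20 (111), against 13.3 expected (exact binomial test, adjusted p = 0.000401). Chemosensory receptors had 6 against 20.4 (exact adjusted p = 0.00233), the strongest near Gr93d (110.3), Or45b (110.1), Ir67b (92.9) and Ir94d (71.9). Eye transcription factors had 0 against 7.64 (exact adjusted p = 0.00501), Hox and homeotic genes 0 against 6.64 (adjusted p = 0.0121), pan-neuronal genes 2 against 10.9 (elav with 198 and Hk with 89; adjusted p = 0.0128), and cytochrome P450 genes 2 against 9.1 (Cyp4d21 with 122 and Cyp6v1 with 77.7; adjusted p = 0.0343). Cuticle genes, low at promoters, had 4 against 8.89 (exact adjusted p = 0.239), near Cpr62Bc (71.1), Cpr62Ba (58.1), Cpr92F (54.7) and Cpr76Bc (49.3).

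Of these calls the EGFR, BMP and Hippo lists each held under 8 of 9 alternatives, the chromatin list under 7, the Notch and ecdysone lists under 3 and the P450 list under 2. In a comparison with the strongest regions that did not pass, which allows for the counting error of both sets, no list was called (Fisher's exact test). The EGFR list stood there at 2.67-fold (30 of 1609 against 10 of 1433, exact p = 0.00604, adjusted p = 0.1702), the BMP list at 1.65-fold (26 against 14, p = 0.151, adjusted p = 0.425) and the Hippo list at 1.78-fold (18 against 9, p = 0.177, adjusted p = 0.455). The dpr, DIP, side and beat list stood at 0.891-fold (exact adjusted p = 1), on 1 summit against 1 region. The other lower lists stayed below 1-fold without being called. The P450 list stood at 0.162 (2 against 11), the chemosensory list at 0.411 (6 against 13) and the pan-neuronal list at 0.445 (2 against 4). The Hox and eye lists had 0 summits against 2 and 3 regions. The Notch and ecdysone calls also ended with the optimal set (exact adjusted p = 0.121 and 0.0826), with replicate 2 alone (0.279 and 0.492), with the stronger peaks (0.577 and 0.216) and with each gene counted once (permutation test, 0.1695 and 0.206), the Notch call with replicate 1 alone (0.436), and the ecdysone call without peaks that rest on shared replicate peaks (0.0708). None of these 6 lower lists passed with replicate 2 alone (exact adjusted p from 0.0664 to 0.279) or with the stronger peaks (0.0831 to 0.437). The Hox (exact adjusted p = 0.0536), pan-neuronal (0.11) and P450 (0.436) calls ended with replicate 1 alone, and the P450 call without peaks that rest on shared replicate peaks (0.0519) and with TSSs up to 50 kb away (0.0556). With each gene counted once the chromatin (permutation test, adjusted p = 0.1504), Hox (0.1695), eye (0.0912), pan-neuronal (0.206) and P450 (0.139) lists were not called.

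**Figure D2:**
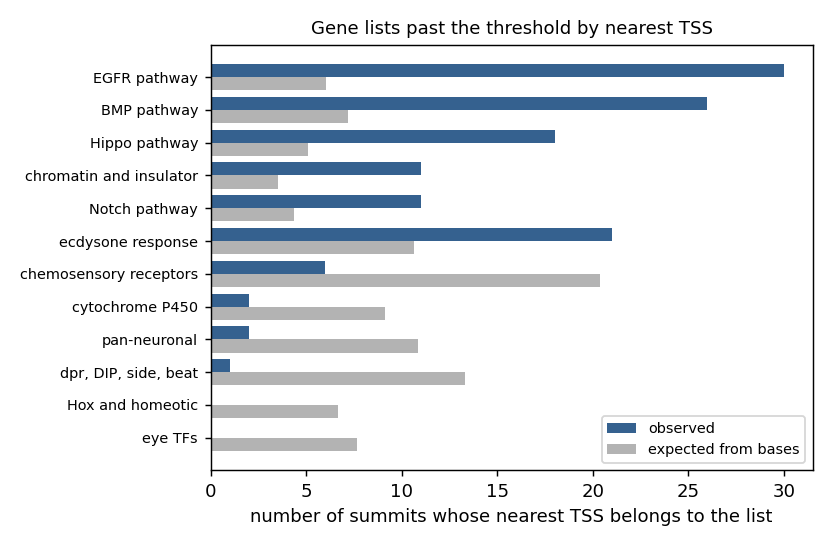
Number of conservative summits whose nearest TSS within 10 kb belongs to each gene list (blue) and the number expected from the list's share of bases (grey), for the 12 lists past the threshold. The EGFR list had 30 summits against 6.04 expected, and the dpr, DIP, side and beat list 1 against 13.3.

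Summits sat on AT-rich sequence. The 100 bp around a summit held 35.1% G and C on average, against 44.8% in the flanks, a deficit of 9.67 percentage points (95% bootstrap interval 9.05 to 10.3, 1799 summits), and 78.8% of summits were below their flanks. The deficit was 12 points in replicate 1 peaks and 11.5 in replicate 2 peaks. Of the 29 consensus sequences 4 were more frequent at summits than in flanks: the homeodomain core TAATTA in 8.95% against 4.2% (exact sign test, adjusted p = 2.06e-08), the GATA-type WGATAR in 21.6% against 14.3% (adjusted p = 4.02e-08), the MEF2 consensus in 5.67% against 2.42% (adjusted p = 5.05e-06) and the TCF consensus in 2.45% against 1.42% (adjusted p = 0.0403).

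The GAGA repeat GAGAGAG (1.11% against 3.89%), CACACACA (1.39% against 5.06%), CAGCTG (2.45% against 5.39%), the proneural E-box RCAGSTG (2.89% against 7.12%) and the Pho core GCCAT (13.2% against 17.6%) were less frequent at summits than in flanks, with adjusted p-values from 2.06e-08 to 0.000295. The other 20 of the 29 consensus sequences did not pass, among them the AT-rich forkhead (5.95% against 4.86%), Exd-Hox (2.95% against 2.53%) and Ohler 6 (1% against 0.584%) sequences, the insulator half-site CGATA (11% against 9.84%, exact adjusted p = 1), the DREF core, and the N-terminal-type and C-terminal-type EVI1 sequences of PRDM proteins. When summit windows were compared with shuffled copies that kept their dinucleotides, in place of flanks, TAATTA was less frequent at summits (8.95% against 11.3%, exact adjusted p = 0.0209), CACACACA more frequent (1.39% against 0.417%, adjusted p = 0.00522), and no other consensus differed at the threshold. The TCF call was lost under all 8 alternatives, the Pho call also with replicate 2 alone (exact adjusted p = 0.133) and in 50 bp windows (0.132), and the GAGAGAG call also for peaks more than 1 kb from a TSS (0.104).

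All 10 of the 6-base sequences that led on 2L, 2R and 4 consisted of A and T, and all 10 passed on 3L, 3R and X (exact sign test, largest adjusted p = 7.05e-14). TTAAAA, for example, was in 32% of 1187 test summits against 13.8% in flanks, and AAATAT in 30.5% against 14.3%. Of the leading 8-base sequences 9 of 10 passed, with ATTTTAAA leading by p (5.98% against 1.64%, exact adjusted p = 2.08e-07). Against dinucleotide-shuffled copies 3 of the 6-base sequences remained higher, AAATAT (30.5% against 21.4%, adjusted p = 1.72e-09), AATATA (adjusted p = 0.00421) and TTTAAA (adjusted p = 0.0319), and 0 of the 8-base sequences did (exact sign test; 1 at an unadjusted p under 0.05, ATTTTAAA, p = 0.0329).

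**Figure D3:**
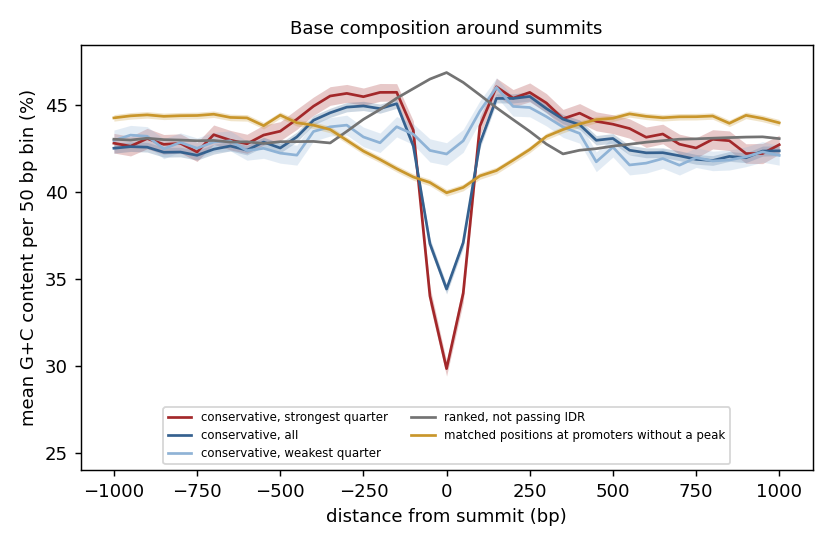
Mean G and C content in 50 bp bins by distance from the summit, with shading for the standard error over regions. The 450 peaks of highest signal fall lowest at the summit (30.8% in the central 100 bp) and the 449 of lowest signal stay near their flanks (42.4%), while regions that did not pass IDR rise at the centre, with 46.7% in the central 100 bp. Peaks that rest on the same replicate peaks as a stronger one are included.

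The tagged gene carried peaks inside it. CG10348 (FBgn0032707) spans 2L 18714453 to 18732524 on the minus strand, and 8 conservative peaks lay in it or within 10 kb. Inside the gene, a peak with signal 78.0 (rank 1068) was in an intron at 18724851 to 18725186, and 1 with 60.7 in a coding exon at 18715049 to 18715384. The intronic region was called in replicate 1 (36.3) and in replicate 2 (43.7), and the peak in the coding exon in neither replicate's own thresholded list. The strongest of the 8, with 468 and 294, lay 8685 and 5746 bp outside the gene, next to the TSSs of Jwa and Faf2. The optimal set had 10 peaks in this range, replicate 1 had 5 and replicate 2 had 4. Of 13945 equal windows of 38072 bp centred on protein-coding genes, 17, this one included, held at least 8 conservative peaks. These windows overlap, and those of neighbouring genes such as Faf2, Grip71 and Irk3 count many of the same peaks. The 17 windows are therefore not separate places. The unbroken run of 10 kb bins that each held a conservative peak extended from 18690001 to 18760000 and contained 17 of them, its edges being set by those peaks. Across that stretch regions that did not pass IDR also had higher signal, with a median of 27.5 (85 regions) against 18.5 (178 regions) in the other bins. Of the neighbouring bins, without a conservative peak, the bin before the stretch had 27.4 and the bin after it 18.6.

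**Figure D4:**
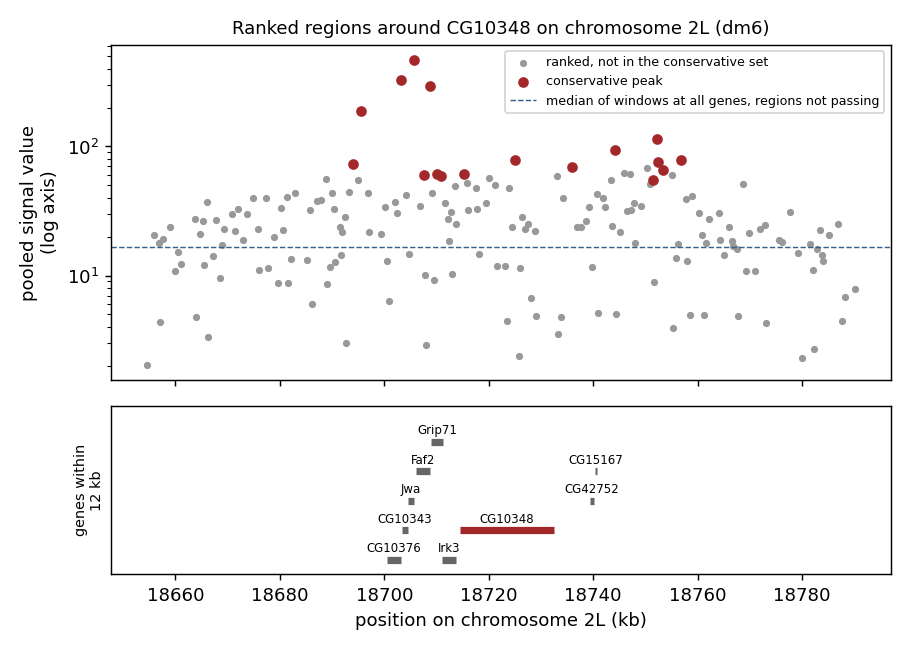
Pooled signal (log axis) of ranked regions by position on chromosome 2L around CG10348, with conservative peaks in red, other ranked regions in grey and genes within 12 kb below. The dashed line, 16.5, is the median over windows at all genes of the signal of regions that did not pass, and the 17 conservative peaks of the stretch lie between 18690001 and 18760000.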

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

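These results come from regions outside the tests, and each was noted because signal was present there. On the main arms, 61 regions reached the lowest score kept by the authors and were absent from the conservative list. The strongest of them, at 2L 480958 to 481237 in an intron 1408 bp from a TSS of cbt, had a pooled signal of 882.1, with 449 in replicate 1 and 444 in replicate 2, and would have had rank 3. Others lay near CG18428 (482), larp (445) and Lk6 (382), and several each near tara, Kdm2 and Rh5, all names chosen after their values were seen. Several more lay on X, 111127 to 324138 bp from the nearest TSS. The thresholded lists were also derived from a further file whose role was not stated. Whether that file removed these regions is unknown. Outside the main arms there were 15 conservative peaks, 1 on Y and 14 on other sequences, with signal up to 403.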

How the results depend on the processing

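Some of these settings were chosen only after the data were seen: IDR 0.001, the dinucleotide-shuffled windows, each gene counted once, the comparison of lists with the strongest regions that did not pass, leaving out peaks that rest on the same replicate peaks, and the peak counts of other sets at CG10348. The promoter excess kept its direction and its side of the threshold under all 9 alternatives, with 23 to 57% of summits at promoters. The planned IDR of 0.01 left the count at 1814 because the authors had already applied it, and an IDR of 0.001 left 803. Overlap of replicate 1 and replicate 2 peaks was 56.8% and 70.3% when at least 50% of both peaks had to overlap, 58.4% and 72.9% for summits within 100 bp, and 67.4% and 84.1% for the stronger peaks of each. Rank agreement was 0.674 for regions passing IDR, 0.189 for those not passing and −0.0936 for the upper part by mean signal. That upper part was selected on the sum of the same log2 signals that were then correlated, which by itself lowers their correlation. The value −0.0936 therefore cannot show that the replicates disagree on stronger regions. Leaving out each replicate gave 1 to 2 arms past the threshold, 1 to 3 lists higher at promoters, 0 to 5 lists lower by nearest TSS and 4 to 5 peaks near CG10348. At promoters 1 list was higher with the optimal set, 1 with genes holding a ranked region as background and 0 within 500 bp. By nearest TSS 0 lists were lower with the stronger peaks, 3 were higher and 2 lower with each gene counted once, and 0 were higher and 0 lower in the comparison with the strongest regions that did not pass, where few regions fell in each list. With shuffled windows 1 consensus was raised and 1 lowered, and 3 of the 6-mers and 0 of the 8-mers remained. The ratio to shuffled windows turned against the ratio to flanks for GAGAGAG (1.72), CAGCTG (1.55), RCAGSTG (1.16), WGATAR (0.895), TAATTA (0.795), CACACACA (3.33) and MEF2 (0.929), where the shuffled windows keep the dinucleotides of the summits and the flanks do not. For the other losses the cause was not tested, though single replicates and stronger peaks leave fewer summits. Depth was unknown and limits what the absence of a peak can show.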

Other observations

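Chosen only after the result was seen were the tests of peaks per gene, of signal rank, of divergent TSSs, of the gene lists taken in parts and of coding exons near CG10348, and the test of windows at CG10348 was chosen after its peaks had been seen. The genes named in this paragraph were also chosen then. Of 1212 genes with a summit nearest to their TSS, 273 had at least 2 and 25 at least 4. The BMP-response regulator shn had 9 (0.815 expected from its bases), Mnt, encoding a Max-binding repressor, 7 (0.475), and Tlk (1.06), shep (1.34) and CHES-1-like (0.468) 6 each. The EGFR-pathway repressor aop had 5 (0.461), as did CBP (0.134), CG5953 (0.457) and Ptpmeg2 (0.547). Among genes with 4 each were brk (0.278), wts (0.176), Raf (0.274) and the ecdysone-induced gene Eip75B (1.42). The others with 4 were CG32512, CG7557, Cyt-c1L, Hipk, Paics, Rtnl1, Shrm, Svil, Unc-76, mtgo, sick and unc-119, with 0.148 to 1.74 expected. Apart from shn, aop, brk, wts, Raf and Eip75B, none of the genes named here belonged to the lists with more summits than expected.

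Promoter location rose with signal. Summits lay within 1 kb of a TSS in 65.6% of the 450 strongest peaks (95% interval 61.1 to 69.8), 48.4% of the next 450, 38.9% of the 450 after them and 38.3% of the 449 weakest (33.9 to 42.9). Of 860 promoter summits, 244 (28.4%, 25.5 to 31.5) lay between divergent TSSs within 1 kb on each side, against 20.3% of positions at the same distance from the TSS of genes without a promoter summit (odds ratio 1.56, Fisher's exact test, p = 2.79e-07).

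The AT-rich sequence under summits was the first pattern weighed. A preference of the libraries or the peak caller for AT-rich DNA in every ranked region is argued against. Ranked regions that did not pass IDR had more G and C at the centre, 46.7% against 43.1% in flanks. The ratio of deficits was −0.374 (95% bootstrap interval −0.399 to −0.35). A bias that recurs in both replicates, as through the shared control, could pass IDR, so this comparison cannot exclude it. That background was also not matched on location, with 18.2% in exons outside promoters against 2.5% of summits. The usual composition of fly promoters is argued against as the whole cause, since matched positions at promoters without a summit had 0.28 of the deficit of promoter summits (0.239 to 0.325), and summits more than 1 kb from a TSS had a deficit of 8.77 points. The deficit was 14.4 points in the 450 strongest peaks, 9.93 in the 450 just above the weakest and 1.59 in the 449 weakest. The weakest had signal from 2.03 to 65.4, and peaks that rest on the same replicate peaks as a stronger one were not left out. How far such peaks account for the low deficit of the weakest was not tested. Dinucleotide composition remains a candidate explanation of the consensus sequences raised over flanks, since 0 of these 4 were called as raised over shuffled windows. TAATTA, WGATAR and MEF2 fell below 1-fold there. The TCF consensus stayed at 1.36-fold (exact sign test, adjusted p = 0.214), and a missed threshold does not decide the question for it. No biological explanation was tested, because the design had 1 group, and open chromatin with an AT-rich core stays open.

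The second pattern was the excess of summits near genes of 6 lists, the EGFR, BMP, Hippo, Notch, ecdysone and chromatin lists. An earlier bound, which took its number from the 6 lists found higher, favoured an explanation if at most 3 of them stayed higher. By it both explanations below were favoured for the 6 lists as a whole, with 3 and 0 lists staying higher. The readings that follow replaced that bound afterwards, and a p that misses the threshold does not show that a list was not higher. With each gene counted once, the EGFR, BMP and Hippo lists stayed higher (permutation test with 10000 draws of genes matched on domain size, largest adjusted p = 0.013). The Notch, ecdysone and chromatin lists were not called (same permutation test, smallest adjusted p = 0.1504, with ratios of 1.81 to 2.47 on few genes). This division of the lists was made after that outcome and matches it, so the result for a part was fixed in advance. Read list by list, several peaks at a few loci are argued against as the whole cause for the EGFR, BMP and Hippo lists. For the Notch, ecdysone and chromatin lists they cannot be told apart from an excess spread over genes. Chromatin that ranks highly whether or not replicates agree cannot be told apart from a specific excess for any of the 6 lists (Fisher's exact test, smallest adjusted p = 0.1702), since the ratio fell for the EGFR (4.97 to 2.67), BMP (3.63 to 1.65), Hippo (3.53 to 1.78), chromatin (3.12 to 1.959) and Notch (2.51 to 1.63) lists and not for the ecdysone list (1.97 to 2.08), all stayed above 1, and the strongest regions that did not pass held only 5 to 14 regions per list. No biological explanation was tested.

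The third pattern was the run of peaks in and beside CG10348. A candidate explanation is extra copies of the locus carried by the tagged transgene, which would raise signal along the whole region. The median signal of regions that did not pass IDR in the window of the gene was above that of 99.7% of equal windows in the pooled list, 98.5% in replicate 1 and 99.9% in replicate 2, where at or below the median would have spoken against it. These windows overlap, so those of neighbouring genes share regions with this one and are not independent of it. Of the 17 conservative peaks in the stretch of 70 kb, 4 lay in coding exons (23.5%), against 2.61% of all 1799 (Fisher's exact test, p = 0.000759). The extent of the transgene was not given in the sources used here, the control was not analysed here, and binding of the protein at its own locus stays open and was not tested.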
